A study of Homo sapiens with 6 samples.

How the data were processed

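PolyA+ RNA of D283 Med cells was profiled by RNA-seq in 6 libraries, 3 transfected with a scrambled LNA GapmeR and 3 with a GapmeR against lncMB3. RNA was extracted with a miRNeasy Micro kit and libraries were made with a TruSeq Stranded mRNA kit, per the labels. Reads were processed by the authors with Trim Galore 0.6.4, STAR 2.7.9a and RSEM on the genome build GRCh38.p13, per the submitters' processing notes. The RSEM version, the gene annotation and whether counting used strand are not given in the sources used here. Each deposited file holds whole-number counts for 60708 genes, which are the unit used here. They are read as RSEM's expected counts, which the authors had rounded before they deposited them. RSEM shares a read among the genes it matches, so counts of near-identical paralogs are uncertain.

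The 44 pseudoautosomal copies on chromosome Y were added to their X copies, which left 60664 genes. Symbols were found for 60463 of them, and coordinates and biotypes for 58396 in GENCODE release 29 (GRCh38, 1-based). Groups and replicate numbers were taken from the labels. Total counts ran from 7765826 to 20035834, so low genes are measured least precisely in knockdown library 1. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 2.81 to 16.5) and each was counted as 1 replicate.

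The groups were compared with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM scaling, and the quasi-likelihood F test (glmQLFit, glmQLFTest) with no covariate. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over 14673 genes, with a threshold of 0.05. Fold changes are knockdown over control, and SE is the log2 change divided by the square root of F, an approximation. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 8.91%. Adjusted p-values in the text are from this test or, for gene lists, from camera in limma 3.58.1.

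Before the data were examined, 29 gene lists were written, of which 28 were tested as sets and the key genes were not. The lists were key genes, TGF-beta pathway components, TGF-beta response genes, photoreceptor programme, Group 3 signature, other subgroup signatures, MYC target genes, ribosomal proteins, ribosome biogenesis, G1/S, G2/M, p53 targets, pro-apoptotic, anti-apoptotic, integrated stress response, endoplasmic reticulum chaperones, heat shock, immediate early, interferon, NF-kappaB, cholesterol synthesis, hypoxia and glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded, neuronal differentiation, neural progenitor, glial, mesenchymal and other markers, and histones. Camera used a preset inter-gene correlation of 0.01, all tested genes as the comparison and Benjamini-Hochberg adjustment over the lists. With it 11 lists were called, 7 up and 4 down. With an estimated correlation 0 lists were called, and 2 had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 13 were called. Counts of list members are of those that passed the low-count filter. It left out most of some lists, with 8 of 47 histones, 14 of 37 interferon genes and 5 of 16 mesenchymal and other markers measured. Of photoreceptor genes 22 of 45 were measured, of glial markers 6 of 13 and of NF-kappaB genes 8 of 20. A list score is the mean log2 CPM of its measured members (prior count 2) relative to the mean of the 6 libraries. The smallest p an exact permutation of 3 against 3 libraries can give is 0.1, so scores carry no p here.

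The named genes were the key genes, the 10 largest rises and 10 largest falls (adjusted p under 0.05, mean of at least 5 CPM, a symbol, groups not overlapping), the 3 largest long non-coding falls with a mean of at least 1 CPM, and up to 4 members per list with the smallest adjusted p. This rule was set before the data were examined. Some genes that it names are not reported here.

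The test was tried on simulated counts of 14673 genes, 3 against 3, with 200 seeded genes and a list of 40 further genes shifted 1.3-fold. It recovered 68 of 100 changed 1.5-fold and 84 of 100 changed 2-fold, 18 more of its 177 calls were in the list, and 7 (3.95%) were in unchanged genes. The list was called by camera, and 0 of 27 unshifted lists were. Simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.925 (ribosomal proteins). The simulation therefore cannot show how often camera calls unshifted lists of correlated genes.

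Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, an adjusted p under 0.01, camera with an estimated correlation, and fry. Corrections for gene span, transcript length and GC content, and the count of lists called by camera on voom values, were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and the closing tests used numpy 2.4.6 and pandas 2.3.3.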

Results

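Polyadenylated RNA was sequenced from D283 Med cells, a human medulloblastoma line with an amplified MYC gene that belongs to the Group 3 subtype. The cells were transfected with LNA GapmeRs, antisense oligonucleotides that direct RNase H to a transcript. In 3 libraries the GapmeR had a scrambled sequence (controls), and in 3 it was directed against the long non-coding RNA lncMB3 (knockdown). Total gene counts were 17072573, 20035834 and 17351552 in controls 1 to 3 and 7765826, 19989654 and 19306711 in knockdown libraries 1 to 3. Knockdown library 1 therefore gave the least precise counts. Mitochondrially encoded genes took 6.37%, 6.26% and 5.84% of counts in the controls and 6.05%, 5.38% and 6.03% in the knockdown libraries. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The gene identifier of lncMB3 is not given in the sources used here, and its own level was not analysed here. Directions are therefore drawn from the group labels.

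The comparison asked which transcripts differ between cells given the GapmeR against lncMB3 and cells given the scrambled one. Loss of lncMB3 cannot be told apart here from other effects of that GapmeR. A large part of the transcriptome differed between the groups by small amounts. Genes of the integrated stress response, photoreceptor genes and hypoxia genes were lower, and genes of ribosome biogenesis, MYC target genes and heat shock genes were higher, by a set test with a preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.332 for each, 0.636 for hypoxia genes). MYC itself was at 1177 ± 90.5 CPM in controls and 1203 ± 74.8 CPM in the knockdown (SD, n = 3 each). Of 14673 genes tested, 4657 (31.7%) passed an adjusted p of 0.05, 2328 higher and 2329 lower, and 511 of them differed at least 2-fold, 128 higher and 383 lower. With upper-quartile scaling, 4576 genes passed, 1773 higher and 2803 lower, so the even split of directions depends on the scaling. In 6746 genes (46%) the 2 groups did not overlap, where chance gives 10%. The first principal component held 53.3% of the variance and separated the groups, with controls at -14.5, -30.7 and -35.4 and knockdown libraries at 31.7, 20.8 and 28. Control 1 was the control nearest to the knockdown libraries. The count fell to 2704 without control 2 (1264 higher, 1440 lower) and to 2891 without control 3 (1420 higher, 1471 lower).

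**Figure D1:**
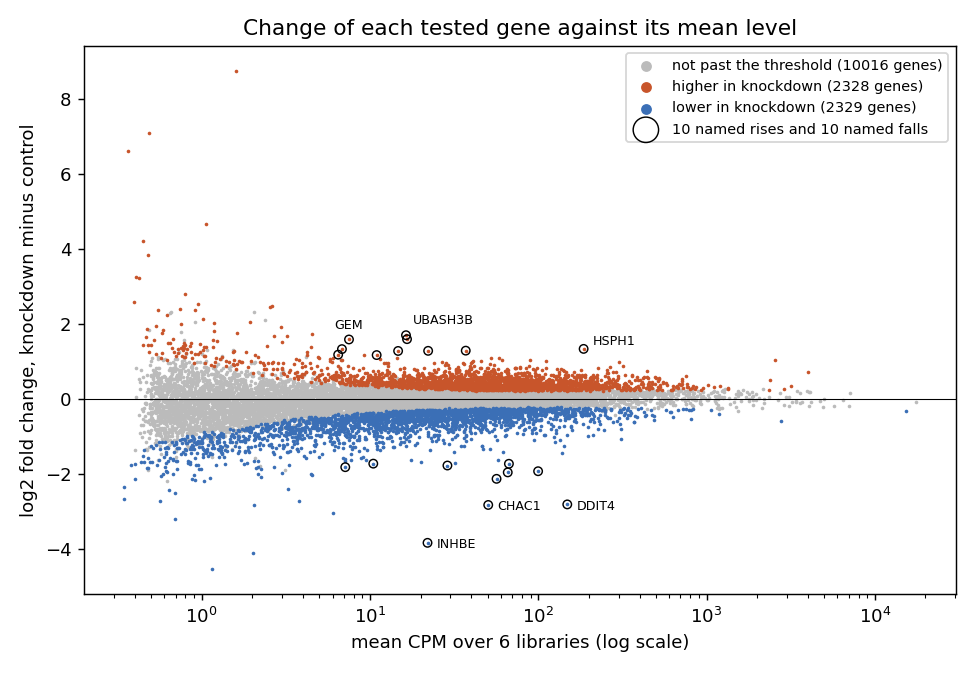
Log2 fold change (knockdown minus control) of each of the 14673 tested genes against its mean normalised CPM over the 6 libraries on a log scale, with genes past an adjusted p of 0.05 coloured by direction (2328 higher, 2329 lower). Open circles mark the 10 named rises and 10 named falls, of which INHBE, CHAC1 and DDIT4 lie lowest.

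Key genes of this tumour type and of cell survival had been fixed for the comparison. MYC (chromosome 8, 127735434 to 127741434), the amplified oncogene, had a log2 change of 0.03 ± 0.09 (SE, adjusted p = 0.826), and PVT1, the long non-coding gene next to it, one of 0.04 ± 0.11 (adjusted p = 0.824). With a gene-span correction PVT1 was at 0.28 (adjusted p = 0.0456). The transcription factors of the photoreceptor lineage were lower. OTX2 (chromosome 14, 56799905 to 56810479) went from 885 ± 51.5 to 729 ± 11.2 CPM, a fall of 1.21-fold (adjusted p = 0.0202). CRX (chromosome 19, 47819779 to 47843330) went from 51.0 ± 10.3 to 37.6 ± 0.671 CPM (adjusted p = 0.0132), and NRL from 6.60 ± 1.31 to 4.29 ± 1.19 CPM (adjusted p = 0.0226), with overlapping libraries for NRL. PCK2, which fell from 158 to 41.7 CPM, lies within the span of NRL on the other strand. The fall of NRL is therefore uncertain, because the counting is not stated to use strand. CDKN1A, a cell cycle inhibitor, rose from 292 ± 16.1 to 355 ± 11.9 CPM (adjusted p = 0.0178). HMGN5, a nucleosome-binding protein, had a log2 change of 0.18 ± 0.18 (adjusted p = 0.486), and BCL2, an inhibitor of apoptosis, one of -0.08 ± 0.16 (adjusted p = 0.717). Some of these calls were lost when 1 library was left out. The adjusted p of OTX2 was 0.107 without control 2, 0.0689 without control 3, 0.0762 without knockdown library 1 and 0.062 without knockdown library 3, but its log2 change stayed at -0.25, -0.26, -0.27 and -0.28 in place of -0.28. For CDKN1A the adjusted p was 0.108, 0.0631, 0.0616 and 0.0789 in the same order, with log2 changes of 0.25, 0.27, 0.28 and 0.25 in place of 0.28. For CRX it was 0.0743 without control 3, with a log2 change of -0.28 in place of -0.44, and for NRL it was 0.0988 without control 2, 0.0808 without control 3 and 0.122 without knockdown library 3, with log2 changes of -0.60, -0.61 and -0.49 in place of -0.69.

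**Figure D2:**
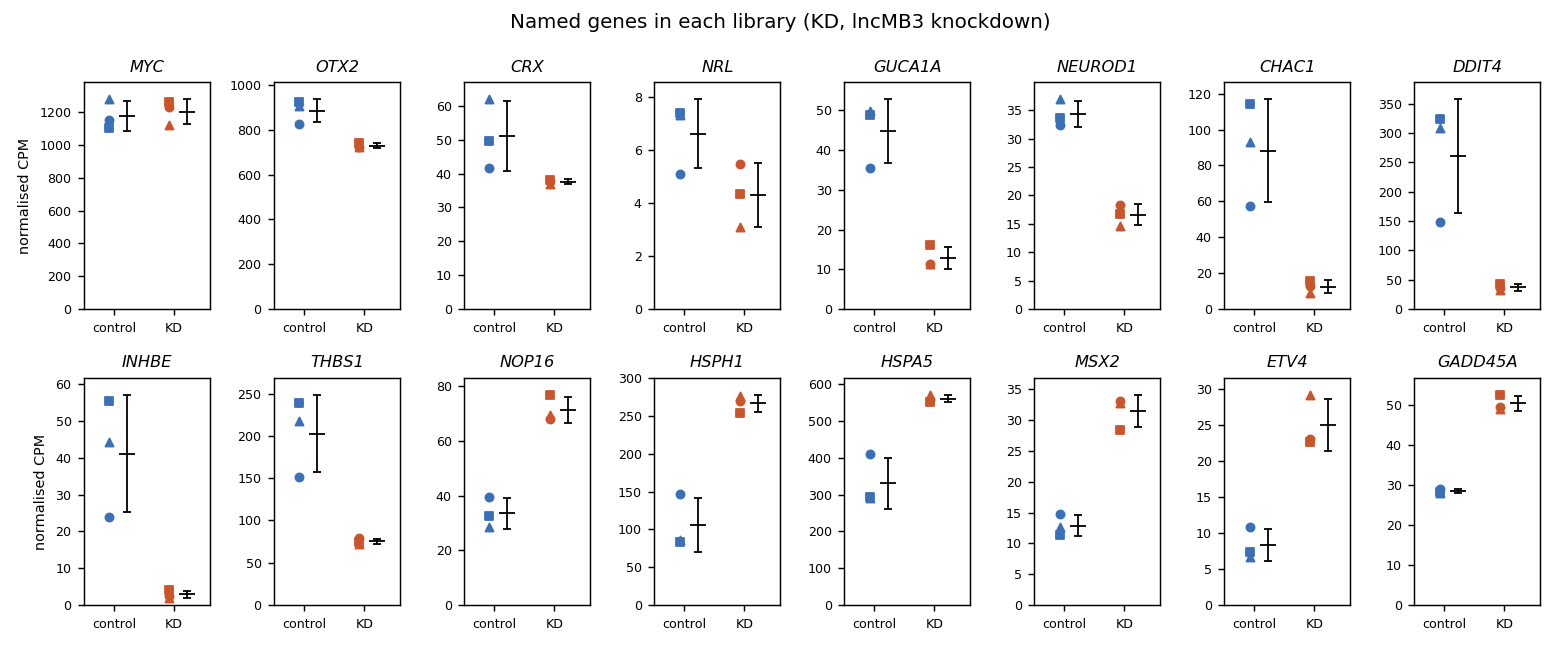
Normalised CPM of 16 named genes in each library, controls in blue and knockdown (KD) in orange, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD (n = 3). MYC overlaps between groups at 1177 and 1203 CPM, DDIT4 falls from 260 to 37.2 CPM, and HSPH1 rises from 105 to 267 CPM.

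Each of the 10 largest falls under the naming rule exceeded the largest rise. INHBE, which encodes an inhibin beta subunit (chromosome 12, 57452323 to 57459280), fell 14.2-fold, from 41.1 ± 15.96 to 2.82 ± 1.06 CPM (log2 change -3.83 ± 0.30, adjusted p = 1.51e-05). CHAC1, a glutathione-degrading enzyme (chromosome 15, 40952962 to 40956519), fell 7.06-fold and DDIT4, an inhibitor of mTORC1 (chromosome 10, 72273920 to 72276036), 6.99-fold, both with an adjusted p of 1.51e-05. ARG2, NDRG1, PCK2, AKNA, GUCA1A, DCT and SLC13A2 completed the 10 largest falls, with log2 changes from -2.12 for ARG2 to -1.72 for SLC13A2. DCT, a melanin synthesis enzyme, went from 103 ± 11.5 to 31.0 ± 2.38 CPM and had the smallest adjusted p of these, 7.83e-07. The 10 largest rises were UBASH3B, ETV4, GEM, HSPH1, KIF5C, SOX8, MSX2, BAMBI, MFSD2A and SPRY4, from 3.27-fold for UBASH3B to 2.26-fold for SPRY4. ETV4, an ETS transcription factor, went from 8.29 ± 2.18 to 24.9 ± 3.65 CPM (adjusted p = 3.27e-05). MSX2, a homeobox factor, went from 12.8 ± 1.72 to 31.5 ± 2.62 CPM (adjusted p = 2.22e-05). In all 20 genes the 3 knockdown libraries lay on one side of the 3 controls, as the rule for naming them required.

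Genes of the integrated stress response, which are switched on through ATF4 when cells lack amino acids or fold proteins poorly, were lower. Of 30 measured members 22 fell and 0 rose, and 23 fell when adjusted over the list alone. The list stood apart from other genes with the preset correlation (adjusted p = 6.36e-17) but not with an estimated one (adjusted p = 0.332 with an estimated correlation). CTH, an enzyme of cysteine synthesis, fell 2.65-fold from 89.2 ± 22.01 to 33.8 ± 2.23 CPM, and PCK2, the mitochondrial PEP carboxykinase, 3.78-fold from 158 ± 52.6 to 41.7 ± 6.05 CPM. Hypoxia and glycolysis genes were also lower, with 10 of 23 measured members falling and 1 rising, the same counts when adjusted over the list alone (adjusted p = 0.00427; adjusted p = 0.636 with an estimated correlation). Fry did not call this list (adjusted p = 0.166), and 7 of the 10 splits of the 6 libraries into 3 and 3 gave a p as small, with a highest other median of 0.253 in size against 0.252. Part of the group difference stays between the sides of every other split, so this count does not measure chance alone. NDRG1, a hypoxia-induced gene, fell 3.87-fold, BNIP3L, a mitophagy receptor, 1.596-fold, and PDK1, a kinase that inhibits pyruvate dehydrogenase, 2.01-fold. Control 1 lay nearer the knockdown libraries than the other controls in both lists. Its mean stress response score was 0.07, against 0.62 and 0.41 in controls 2 and 3 and -0.38, -0.27 and -0.44 in the knockdown libraries. Its hypoxia score was -0.06, against 0.12 and 0.45 in controls 2 and 3 and -0.21, -0.12 and -0.18 in the knockdown libraries. Without control 3 the median hypoxia change was -0.13 in place of -0.25.

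Photoreceptor genes, whose activity marks Group 3 tumours, were lower as a group. Of 22 measured members 16 fell and 0 rose, also when adjusted over the list alone (median log2 change -0.81, adjusted p = 3.08e-11; adjusted p = 0.332 with an estimated correlation). GUCA1A, a guanylate cyclase activator, fell 3.41-fold from 44.8 ± 8.07 to 13.0 ± 2.74 CPM, and GNB3, a cone transducin subunit, 3.10-fold. Neuronal differentiation genes showed 8 falls and 1 rise among 19 measured members, the same when adjusted over the list alone (adjusted p = 0.0021; adjusted p = 0.332 with an estimated correlation). NEUROD1, a neurogenic factor held by both lists, fell 2.09-fold from 34.3 ± 2.36 to 16.6 ± 1.83 CPM. The neurofilament genes moved apart, with NEFL falling 1.55-fold and NEFH rising 1.55-fold. The Group 3 signature was not called (adjusted p = 0.12), though 6 of its 10 measured members fell and 1 rose, also adjusted over the list alone, and it was called with no low-count filter (adjusted p = 0.0294). IMPG2, a photoreceptor matrix protein, fell 1.51-fold, and GABRA5, a GABA receptor subunit, rose 1.33-fold. Signatures of the other subgroups were not called either (3 falls and 0 rises of 13, also adjusted over the list alone, adjusted p = 0.158, and 0.0244 by fry), with GLI1, a Sonic hedgehog effector, falling 2.29-fold. Markers of other cell types were measured beside these genes. Of 5 mesenchymal, endothelial, immune and epithelial markers 3 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0838, and 0.0122 by fry), among them KRT8, 1.599-fold. Glial markers gave 1 rise and 2 falls of 6, also adjusted over the list alone (adjusted p = 0.221, and 0.042 by fry), and neural progenitor markers 1 rise and 1 fall of 11, or 1 and 0 adjusted over the list alone (adjusted p = 0.472). The photoreceptor score of control 1 was 0.25, against 0.52 and 0.48 in controls 2 and 3 and -0.53, -0.28 and -0.43 in the knockdown libraries.

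**Figure D3:**
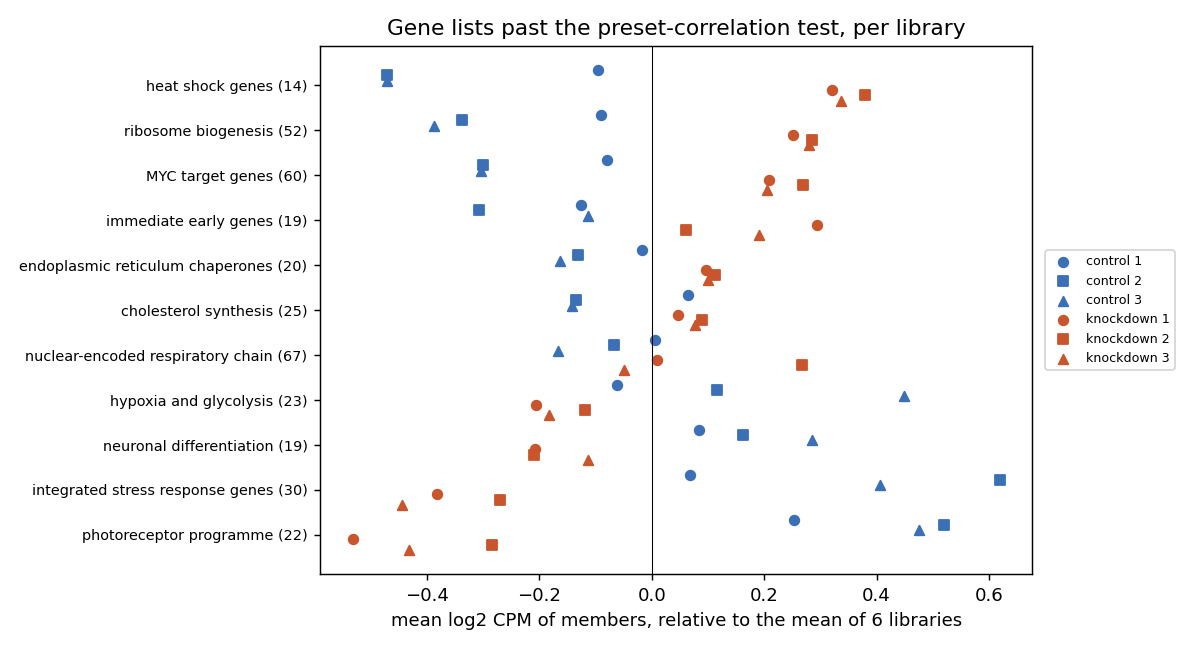
Mean log2 CPM of the members of the 11 gene lists past the preset-correlation test, relative to the mean of the 6 libraries, with controls in blue, knockdown in orange, circles, squares and triangles for replicates 1, 2 and 3, and the number of measured members in brackets. For the integrated stress response control 1 lies at 0.07, between 0.41 and 0.62 in the other controls and the knockdown libraries at -0.44 to -0.27.

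Genes for making ribosomes were higher, while the ribosomal proteins themselves gave no called member. Of 52 measured ribosome biogenesis genes 47 rose and 0 fell, and 49 rose when adjusted over the list alone (median log2 change 0.54, adjusted p = 5.34e-27; adjusted p = 0.332 with an estimated correlation). WDR75, a small-subunit processome factor, rose 1.84-fold from 62.0 ± 10.5 to 114 ± 6.52 CPM, and LTV1, a small-subunit assembly factor, 2.03-fold. MYC target genes, many of them nucleolar, showed 46 rises and 0 falls of 60, and 49 rises when adjusted over the list alone (adjusted p = 6.66e-22; adjusted p = 0.332 with an estimated correlation). NOP16, a nucleolar protein, rose 2.14-fold from 33.5 ± 5.64 to 71.5 ± 4.76 CPM, and NOP2, an rRNA methyltransferase, 2.05-fold. Of 79 ribosomal protein genes 0 passed edgeR's test, also adjusted over the list alone, and 4 had an unadjusted p under 0.05. DESeq2 and limma-voom called 0 as well, and the list was not called (adjusted p = 0.151). Its adjusted p was 0.0086 without knockdown library 1 and 0.00252 without knockdown library 3, and without knockdown library 2 its median turned from 0.08 to -0.05. Control 1 again lay nearer the knockdown libraries, with a ribosome biogenesis score of -0.09, against -0.34 and -0.39 in controls 2 and 3 and 0.25, 0.29 and 0.28 in the knockdown libraries.

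Chaperone genes were higher. Of 14 heat shock genes 11 rose and 0 fell, and 12 rose when adjusted over the list alone (adjusted p = 3.88e-10; adjusted p = 0.332 with an estimated correlation). HSPA8, the constitutive HSP70, rose 2.05-fold from 1669 ± 372 to 3425 ± 154 CPM, HSPH1, its nucleotide exchange factor, 2.54-fold, and DNAJA1, an HSP70 co-chaperone, 1.86-fold. HSPA1A shares reads with a near-identical paralog and its 1.79-fold rise is uncertain. The heat shock score of control 1 was -0.10, against -0.47 in each of the other controls and 0.32, 0.38 and 0.34 in the knockdown libraries. Endoplasmic reticulum chaperones gave 10 rises and 2 falls of 20, or 12 and 3 adjusted over the list alone (adjusted p = 0.00593; adjusted p = 0.332 with an estimated correlation), with HSPA5, the chaperone BiP, rising 1.69-fold from 331 ± 69.0 to 560 ± 9.63 CPM.

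Immediate early genes gave 6 rises and 0 falls of 19, also adjusted over the list alone (adjusted p = 0.0327; adjusted p = 0.332 with an estimated correlation). JUNB, an AP-1 subunit, rose 1.44-fold and DUSP5, an ERK phosphatase, 1.86-fold, while ARC was near the detection floor at 0.117, 0.049 and 0.056 CPM in the controls and 0.650, 0.782 and 0.782 CPM in the knockdown. The call of the list was lost without control 1 (adjusted p = 0.0707, median 0.29 in place of 0.26) and without knockdown library 1 (0.0576, median 0.21). It was kept without knockdown library 3 (adjusted p = 0.0288), where the median was 0.10. The 6 libraries can be split into 3 and 3 in 10 ways, the real one included. Of these, 3 gave immediate early genes an unadjusted camera p as small as the real one. Part of the group difference stays between the sides of every other split, so such counts do not measure chance alone. Cholesterol synthesis genes gave 10 rises and 2 falls of 25, or 12 and 3 adjusted over the list alone (adjusted p = 0.037, and 0.137 by fry; adjusted p = 0.636 with an estimated correlation). HMGCS1, HMG-CoA synthase, rose 1.58-fold and IDI1, an isopentenyl diphosphate isomerase, 1.52-fold, while TM7SF2, a sterol reductase, fell 1.55-fold. The cholesterol call was lost without control 2 (adjusted p = 0.0912, median 0.15 in place of 0.23), control 3 (0.0698, median 0.20) or knockdown library 2 (0.0875, median 0.20), and control 1 scored 0.06 against -0.13 and -0.14 in the other controls. Of the 10 splits 4 gave cholesterol synthesis an unadjusted camera p as small as the real one (smallest other adjusted p = 0.000132). Nuclear-encoded respiratory chain genes gave 14 rises and 0 falls of 67, or 0 of either adjusted over the list alone (adjusted p = 0.0028, and 0.306 by fry; adjusted p = 0.747 with an estimated correlation). That call was lost without knockdown library 2 (adjusted p = 0.271, median 0.05 in place of 0.16), which scored 0.27 against 0.01 and -0.05 in the other knockdown libraries. Of the 10 splits 8 gave nuclear-encoded respiratory chain genes an unadjusted camera p as small as the real one (smallest other adjusted p = 1.26e-15). Their median reached 0.19 in size in another split, against 0.159. SDHB, a succinate dehydrogenase subunit, rose 1.32-fold. Mitochondrially encoded genes gave 1 rise and 1 fall of 13, also adjusted over the list alone (adjusted p = 0.298), and the list was called without knockdown library 2 (adjusted p = 0.0466).

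Signalling, cell cycle and cell death genes moved in both directions, as did tested genes as a whole (31.7% called, 2328 higher and 2329 lower). TGF-beta pathway components gave 4 rises and 4 falls of 32, or 3 and 4 adjusted over the list alone, with a median of -0.07 and a mean of 0.02 that differ in sign and a test that pointed down (adjusted p = 0.812). BMPR1A, a BMP receptor, rose 1.55-fold and SMAD6, an inhibitory SMAD, 1.53-fold, while SMAD3, which transmits TGF-beta signals, fell 1.46-fold. TGF-beta response genes gave 9 rises and 5 falls of 21, or 10 and 5 adjusted over the list alone (adjusted p = 0.14, and 0.0122 by fry). ID3, an inhibitor of DNA binding, rose 1.65-fold and CCN2, a matricellular protein, 2.14-fold, while THBS1, thrombospondin, fell 2.71-fold from 203 ± 45.9 to 75.1 ± 3.22 CPM. Target genes of p53 gave 8 rises and 3 falls of 29, or 9 and 3 adjusted over the list alone (adjusted p = 0.0838, and 0.0122 by fry). GADD45A, a growth arrest gene, rose 1.77-fold from 28.4 ± 0.525 to 50.4 ± 1.85 CPM and PLK2 1.78-fold, and SESN2, a stress-inducible inhibitor of mTORC1, fell 1.95-fold. Pro-apoptotic genes gave 4 rises and 5 falls of 26, also adjusted over the list alone (adjusted p = 0.812), with BAX rising 1.37-fold and CASP8 falling 1.84-fold. Their median was 0.10 and their mean -0.01. Anti-apoptotic genes gave 2 rises and 2 falls of 14, also adjusted over the list alone (adjusted p = 0.812), with MCL1 rising 1.304-fold and BCL2L1 falling 1.41-fold. Their median was 0.10 and their mean -0.03, and in both lists the test pointed up, against the sign of the mean.

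Genes of the G1/S transition gave 11 rises and 1 fall of 43, or 10 and 1 adjusted over the list alone (adjusted p = 0.0773, and 0.018 without control 1, 0.0343 with no low-count filter and 0.0464 with limma-voom), with CLSPN, a replication checkpoint mediator, rising 1.39-fold and PRIM1, a primase subunit, falling 1.31-fold. G2/M genes gave 7 rises and 1 fall of 54, or 5 and 1 adjusted over the list alone (adjusted p = 0.204), with CKS2, a CDK subunit, rising 1.42-fold. Interferon response genes gave 0 rises and 3 falls of 14, also adjusted over the list alone (adjusted p = 0.141), with STAT2, an interferon signal transducer, falling 1.45-fold. NF-kappaB response genes gave 1 rise and 2 falls of 8, also adjusted over the list alone (adjusted p = 0.812), with IER3 rising 1.79-fold and NFKB2 falling 1.49-fold. Their median was 0.04 and their mean -0.11, with a test that pointed up. Replication-dependent histones, most of which lack a polyA tail, gave 1 rise of 8, H2BC8 from 0.637 ± 0.164 to 1.71 ± 0.354 CPM, also adjusted over the list alone (adjusted p = 0.308).

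Long non-coding RNA genes were more often lower than higher. Of 1190 tested 165 fell and 63 rose, with a median log2 change of -0.20, against 2123 falls and 2211 rises of 12716 protein-coding genes. The long non-coding genes were measured at a median of 1.6 CPM and protein-coding genes at 27 CPM. Sets of protein-coding genes matched on expression had a median log2 change of -0.159, against -0.203 for the long non-coding genes. LINC00907 (chromosome 18, 42159283 to 42691422) went from 1.70 ± 0.587 to 0.373 ± 0.0543 CPM, a fall of 2.19 ± 0.40 on the log2 scale (adjusted p = 0.00117). ENSG00000214708, an antisense gene on chromosome 17 (32141226 to 32143135), went from 3.75 ± 0.574 to 0.782 ± 0.455 CPM (adjusted p = 0.000337). ENSG00000270696, an antisense gene on chromosome 2 (75660462 to 75662208), went from 3.59 ± 1.301 to 0.748 ± 1.29 CPM (adjusted p = 0.0331), and its adjusted p was 0.0573 without control 1, 0.128 without control 2, 0.0704 without knockdown library 1, 0.101 without knockdown library 3 and 0.488 by DESeq2. All of its knockdown counts came from knockdown library 2 (2.24 CPM), the others held 0, and its adjusted p was 0.000395 without that library. Its log2 change moved from -2.00 to -1.31 without knockdown library 3. Both antisense genes are uncertain, because the counting is not stated to use strand.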

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

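The corrections for gene span, transcript length and GC content, and the count of lists called on voom values, were chosen after seeing the data. Over 136 named genes, 2166 comparisons with other settings were made. Of these 2051 kept direction and side of the threshold, 86 lost the call, 18 gained one and 11 changed sign. Of 116 called genes 89 kept their call in every refit that gave them an adjusted p. These comparisons use the threshold of 0.05 and leave out the stricter one of 0.01. Each sign change among named genes and lists was in one that had not been called, and the cause was not tested. Of all 4657 called genes 19 changed sign with the gene-span correction, and 0 with any other setting run. DESeq2 found 337 genes changed at least 2-fold, against 511. At an adjusted p under 0.01, 2459 genes passed, 1190 higher and 1269 lower. With an estimated correlation 0 lists passed camera (2 at an unadjusted p under 0.05), and 13 passed fry, which gained the TGF-beta response, other subgroup, p53, glial and mesenchymal and other marker lists and lost the cholesterol, hypoxia and respiratory chain lists. Leaving out 1 library gave 2704 to 5114 changed genes, 1264 to 2604 higher and 1440 to 2510 lower, lowest without control 2 and highest without control 1. The replicate block gave 4742 changed genes. With the group mean of each gene taken off, same-numbered libraries correlated at 0.031, 0.096 and -0.033. They were not best with their own number in every sample, so the numbers were not taken as pairs.

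MYC was -0.02743 with upper-quartile scaling, -0.01305 with the gene-span correction and -0.01592 to 0.09353 when 1 library was left out. For PVT1 the values were -0.02109 with upper-quartile scaling, 0.2808 with the gene-span correction (adjusted p = 0.0456, a gained call) and -0.03381 to 0.0779 with 1 library left out. BCL2 was 0.08811 with the gene-span correction and -0.1875 to 0.09095 with 1 library left out, and HMGN5 -0.01257 to 0.3666. MSI2 was 0.08326 with the gene-span correction. The direction of the list test turned for NF-kappaB with voom (median 0.0418) and for pro-apoptotic genes (0.0552) and TGF-beta components (0.0217) with the gene-span correction. It also turned without knockdown library 2 for TGF-beta components and ribosomal proteins, whose medians ran from -0.161 to -0.0198 and from -0.0469 to 0.159 with 1 library left out. Without a low-count filter the Group 3 and G1/S lists were called (adjusted p = 0.0294 and 0.0343). The immediate early and cholesterol lists lost their calls with a filter of 1 CPM in 3 libraries (adjusted p = 0.0651 and 0.0549) and with the gene-span correction (0.121 and 0.125). Unrounded counts were not run because the values are whole, and DESeq2 gives no list test. Depth limits genes near 1 CPM most, in knockdown library 1.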

Other observations

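The tests of the splits, of control 1, of gene span and its correction, and of matched expression were chosen after the results they bear on were seen, except the test of the span slope in control 1. The gene groups of the next 2 paragraphs were also chosen after their values were seen.

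Several genes that BMP signalling induces rose, where 2328 of all 14673 tested genes did. The groups of this paragraph were not tested as sets. Of 10 measured, 8 rose and 0 fell: MSX2, BAMBI, NOG, ID3, ID1, SMAD6, SMAD7 and ID2, with NOG, a secreted BMP antagonist, rising 1.72-fold from 24.7 ± 1.35 to 42.9 ± 5.12 CPM (SD, n = 3 each, edgeR adjusted p = 0.000158) and ID1 1.503-fold. ID4 and MSX1 had log2 changes of 0.21 ± 0.23 and 0.07 ± 0.12. Of 10 genes of the feedback on ERK signalling 4 rose and 0 fell: ETV4, SPRY2, SPRY4 and DUSP5, with SPRY2, an inhibitor of receptor tyrosine kinase signalling, rising 1.87-fold from 20.3 ± 1.57 to 37.9 ± 3.99 CPM (adjusted p = 8.33e-05). ETV5 and SPRED2, of the same group, had log2 changes of -0.05 ± 0.13 and -0.01 ± 0.09. Host genes of small nucleolar RNAs gave 12 rises and 2 falls of 25. SNHG12 rose 1.96-fold from 19.1 ± 0.491 to 37.3 ± 3.45 CPM, and SNHG29 and SNHG32 fell 1.26-fold and 1.35-fold.

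A few genes were absent from the controls. In 3 called genes, GARIN4, FGF18 and GP5, all 3 controls held 0 counts and all 3 knockdown libraries held some. GARIN4 reached 3.21 ± 0.443 CPM in the knockdown from 146 counts, at least 59.4-fold higher against a floor of 3 counts over the control group, FGF18, a growth factor, at least 18-fold from 47 counts, and GP5, a platelet glycoprotein, at least 13.5-fold from 33 counts. Floors cover counting error only. In 0 called genes were all knockdown libraries at 0. FGF21, a secreted factor that ATF4 induces, was at 1.05, 3.42 and 2.07 CPM in the controls and 0.260, 0.104 and 0 CPM in the knockdown (adjusted p = 0.000367).

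Only the real split of the 6 libraries into 3 and 3 gave changed genes. It was 1 of 10 splits with as many changed genes (4657, highest other 0), and likewise 1 for genes higher (2328), lower (2329) and changed at least 2-fold (511). Of the 10 splits 4 gave as many gene lists as the real one (11, highest other 14). Camera with the preset correlation called ribosome biogenesis in 9 other splits (smallest other adjusted p = 3.99e-14) and MYC targets in 8 (3.94e-14). It called the photoreceptor list in 7 other splits (6.2e-06), the stress response in 6 (3.49e-13) and heat shock in 5 (3.31e-06). For each of these lists the real split had the smallest p. With 10 splits the share is never under 0.1, too few for a share under 0.05. Every other split also puts libraries of both groups on each side, so the group difference adds to the spread within a side. The 0 changed genes in those splits therefore cannot decide on chance. Part of the group difference also stays between the sides of those splits. Their list calls are therefore not calls made without a group difference, and cannot decide on chance either. The splits with 12, 12 and 14 lists are those that put control 1 with 2 knockdown libraries, which points to a structure of the samples.

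Control 1 lay between the other controls and the knockdown libraries. Its share of the way to the knockdown mean was 0.637 for integrated stress response genes and 0.852 for hypoxia genes, 0.365 for ribosome biogenesis genes and 0.341 (95% interval 0.115 to 0.52) for photoreceptor genes, but controls 2 and 3 also differ from each other in stress minus ribosome share, by -0.469 and 0.349. Lower depth is argued against by its total count, 0.984 of the lower of the other controls. Knockdown RNA mixed into control 1 would move all genes by 1 share, but the 50 largest falls minus the 50 largest rises, chosen without control 1, gave 0.191 (95% interval 0.105 to 0.273) against control 3 and 0.194 (0.107 to 0.275) against control 2; 2 earlier versions of this test, on the 10 named rises and on rises against ribosome biogenesis, and a looser bar for it were replaced after their results were seen. Mixing stays open as the whole cause, since the only other pair of controls gave -0.053 (-0.147 to 0.04) and 0.052 (-0.038 to 0.143), of which the second interval overlaps both of these, and as part of the shift, since the rises lay at 0.256, and a state of the cultures that varies without the knockdown may be involved, since control 1 minus control 2 correlated across genes with knockdown minus control 3 at r = 0.403, which mixing would give too, and genes are not independent replicates.

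Genes with long spans were lower in the knockdown. The log2 change fell by 0.164 per 10-fold longer span, and by 0.093 without knockdown library 2, with a median of 0.09 in the shortest eighth of protein-coding genes and -0.21 in the longest, where 532 fell and 71 rose. With transcript length, GC content and expression level all in the model the slope was -0.231, which argues against these 3 as the whole cause. The slope of control 1 against the other controls was -0.025, or 15.2% of -0.164. No SE was computed for it, and the group slope itself shrank to -0.093 without knockdown library 2. It therefore cannot decide on the shift of control 1 as a cause. Differences between libraries stay open: slopes within a group differed by up to 0.159, nearly the group difference, although 9 of 9 pairs of a knockdown and a control library had a negative slope (-0.256 to -0.064). An effect of the knockdown on long genes is a hypothesis that stays untested beside it.

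Photoreceptor and neuronal genes include long ones, so their fall could be the span trend. After the span correction the photoreceptor median was -0.711 (adjusted p = 3.71e-11) and the neuronal median -0.351 (adjusted p = 0.00273) with the preset correlation, which argues against the trend as the whole cause, although both list calls are lost with an estimated correlation (adjusted p = 0.332 for each, without the span correction). EYS, a very long photoreceptor gene, lost its call under it: its log2 change moved from -0.81 ± 0.17 to -0.27 ± 0.17 (SE, adjusted p = 0.239), so the change shrank and its SE did not grow. Control 1 lay 0.341 of the way to the knockdown mean for photoreceptor genes, so the open explanations for control 1 bear on this list too, and an effect of the knockdown itself stays open, untested.

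The fall of long non-coding genes was compared with protein-coding genes of matched expression. Their median was -0.203, and 10000 matched sets had a median of -0.159, of which 146 lay at or below -0.203. Protein-coding genes of like expression were thus lower too, and only the gap between -0.159 and -0.203 sets long non-coding genes apart. The matched sets treat genes as independent, so 146 of 10000 does not measure the spread between libraries.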
